A study of Bos taurus with 9 samples.

How the data were processed

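RNA was profiled in mesenchymal stem cells grown out of bovine subcutaneous fat. The 9 libraries form 3 groups of 3: a pooled CRISPR knockout population at day 125 (library knockout day 125), unedited cells at the same day (wild type day 125) and unedited cells at day 25 (wild type day 25). Per the labels, the pool was made with Cas9 and guides against 600 genes, cells were passaged every 5 days for 100 days at a seeding density of 3500 cells per square centimetre, and total RNA came from 5000000 cells per sample. The labels print the same transduction text on all 9 samples. Which libraries received the vectors was therefore taken from the genotype and title alone, and no library is labelled as a transduction control. Nothing in the labels says that the 3 replicates of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

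The deposited unit is raw counts per gene, 1 whole number per gene and library, which the authors made from MARS-seq2.0 libraries, a 3' end method, per the labels. The genome build was ARS-UCD1.2, per the submitters' processing notes. The aligner, the counting tool, the annotation, any gene filter and the use of molecular identifiers are not given in the sources used here. If identifiers were not collapsed, counts are reads and not independent molecules, and every counting interval or floor covers counting error only. A 3' tag need not cover a guide site, so a count does not measure whether a gene was cut. The table holds 12121 genes by Ensembl identifier, of which 922 carry no symbol and 127 had no count in any library. For 42 repeats of a symbol, the row with the highest total stood for the symbol.

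Total counts per library ran from 977453 to 3553260. In the smallest library 1 count equals 1.04 CPM (counts scaled to a common library total), and in the largest 0.258 CPM. At 10 counts the counting error alone is 31.6%.

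Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 8853 tested and 3268 not tested. Libraries were scaled by TMM (trimmed mean of M values), and all 9 entered 1 quasi-likelihood fit with robust dispersion and group as the only factor. Each of the 3 comparisons was tested 2-sided with Benjamini-Hochberg adjustment over the 8853 genes, at a threshold of 0.05. Of the gene lists, 31 were written down from general knowledge of the cells, the cell cycle, metabolism and other cell types, and the 24 with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes. The same test was run with a correlation estimated from the residuals. Chromosomes were tested as sets in the same way. The table of symbols used for this belongs to another assembly, ARS-UCD2.0, so only chromosome membership and gene order were taken from it. It matched 8231 of the tested genes, and 8229 had a chromosome.

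The genes named were set by a rule: in each comparison the 5 largest rises and the 5 largest falls among genes past the threshold with a symbol, a mean of at least 20 CPM in the higher group and no overlap between the 3 values of either group; the 2 called members with the lowest adjusted p in each of 10 lists; and a fixed set with CDKN1A, MDM2, CDKN2A, CDKN2B, MKI67, CCNB1, IL6, COL1A1, PPARG and ACTA2. For the 10 lists, those with at least 20% of tested members past the threshold and the lowest camera p were taken. Other list members are named as examples chosen after their values were seen. The groups, the tests, the lists, this rule and the alternatives were fixed before the data were examined, except the alternatives said to be chosen later. CDKN2A, CDKN2B, mitochondrial genes and sex-linked marker genes were not analysed here. Some other genes of the rule, 1 gene list and their results are not reported here.

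Replicates were compared before averaging. The chi-square per degree of freedom over genes with at least 20 counts in a pair ran from 1.75 to 10.3 within groups and from 35.6 to 58.1 between groups, so no pair agreed within sampling noise and all 9 libraries were counted.

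The fitting code was tested on simulated data drawn from the real means, library sizes and dispersions with 100 genes changed 2-fold and 100 changed 4-fold. The other genes of chromosome 21 were lowered by 0.3 on the log2 scale and counted as changed. For library knockout against wild type day 125, 65% of 2-fold and 93% of 4-fold changes were recovered among 8624 genes, for library knockout against wild type day 25 68% and 96% among 8639, and for wild type day 125 against day 25 71% and 89% among 8627. Between 5.08% and 5.75% of the genes called were unchanged ones. Far fewer genes were called in these simulations than in the real data, so the recovered shares need not carry over. The alternatives were RLE, upper-quartile and total-count scaling, no low-count filter, a filter at a mean of 20 CPM, DESeq2 1.42.0, limma-voom, fits of 2 groups alone, a replicate block, a prior count of 0.5, ranked and estimated-correlation set tests, and leaving out each library. Thinning every library to the smallest total, and list counts without each library, were chosen after seeing the data.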

Results

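Transcripts were counted in 9 libraries of bovine adipose-derived mesenchymal stem cells, multipotent stromal cells that adhere, divide and can form fat, bone and cartilage. The design text states that the pool was built to learn which genes regulate proliferation of these cells. Total counts were 2668228, 2649167 and 2776632 in wild type day 25, 2891455, 2835629 and 977453 in wild type day 125, and 3553260, 2929880 and 3444701 in library knockout day 125. Replicate 3 of wild type day 125 was thus the shallowest library. Over the 5100 genes with a geometric mean above 20 CPM after TMM scaling, the first principal component (54.7% of the variance) set wild type day 125 apart from the other groups, and the second (32.0%) set library knockout apart from wild type day 25. Below, group values are CPM as mean ± SD over n = 3 libraries, fold changes are log2 with their standard error, and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless camera is named.

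The labels do not name the 600 targets, so no target could be checked against them. IL6, an inflammatory cytokine, and PPARG, the regulator of fat cell formation, were filtered out, with at most 9 and 7 counts in any library.

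Wild-type cells at day 125 were compared with day 25 to show how unedited cells differed after long passage. Cell-cycle, ribosomal and respiratory chain genes were lower after passage, while surface markers of the stem cells and matrix genes were higher. These list calls hold with the preset correlation and were lost with an estimated one (camera adjusted p = 0.194 to 0.390). CDKN1A (ENSBTAG00000008353), the cyclin-dependent kinase inhibitor p21 that halts the cell cycle, rose from 297 ± 19.5 to 1477 ± 119 CPM (2.31 ± 0.19, adjusted p = 4.43e-07). MKI67, a marker of cycling cells, fell from 204 ± 11.5 to 128 ± 8.98 CPM, and CCNB1, the cyclin of mitotic entry, from 73.2 ± 4.06 to 25.2 ± 4.07 CPM (adjusted p = 0.000248 and 3.04e-07). THY1 (CD90) rose from 31.3 ± 3.45 to 1293 ± 57.9 CPM (5.37 ± 0.13, adjusted p = 2.97e-15), and ENG (CD105) fell from 109 ± 5.99 to 3.61 ± 1.2 CPM (-4.96 ± 0.22, adjusted p = 1.11e-11).

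Of the genes tested, 2134 rose and 1983 fell with passage, and 1762 of these changed at least 2-fold. AQP1, a water channel, rose from 3.67 ± 0.240 to 803 ± 90.2 CPM, ACAN, the core protein of cartilage aggrecan, from 3.30 ± 1.78 to 532 ± 17.3. RAMP3, a partner of the adrenomedullin receptor, had 420 counts in wild type day 125 and 2 in day 25, a ratio of 261 with a 95% counting interval of 71.8 to 2163. LGI2 had 359 counts against 2, a ratio of 223 (61.3 to 1850). CRABP1, a retinoic acid binding protein, fell from 691 ± 13.3 to 3.53 ± 1.27 CPM, and the amino acid transporter gene SLC38A5 from 103 ± 5.33 to 0.616 ± 0.564. CPE, a prohormone-processing carboxypeptidase, fell by 6.02 ± 1.10. PARVB, a focal adhesion gene, and ARHGAP24 had 515 and 457 counts at day 25 against 2 and 3 at day 125, ratios of 207 (57.0 to 1715) and 123 (41.7 to 596). The call of VIPR2 (151 counts against 1) was lost when any wild-type library was left out.

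Ribosomal protein genes fell in 58 of 72 tested members, rose in 0 and were not called in 14, with 61 falling adjusted over the list alone. RPL14 fell from 2711 ± 143 to 1053 ± 247 CPM, and RPS27 by 1.53 ± 0.17. Of the nuclear genes of oxidative phosphorylation, 45 of 63 fell and 0 rose (45 and 0 adjusted over the list alone). ATP5MC3, a subunit of ATP synthase, fell by 1.29 ± 0.13 and NDUFB5, of complex I, by 1.01 ± 0.13. Among mitosis genes 23 of 32 fell and 0 rose (24 and 0 adjusted over the list alone), led by the transcription factor gene MYBL2 (-2.22 ± 0.16) and the anaphase activator gene CDC20 (-1.57 ± 0.15). Among DNA replication genes 18 of 33 fell and 0 rose (18 and 0 adjusted over the list alone), including the sliding clamp gene PCNA (-0.99 ± 0.13) and the helicase gene MCM5 (-1.21 ± 0.16). Camera adjusted p was 8.09e-12, 1.15e-08, 1.15e-08 and 0.000139 for the 4 lists, and adjusted p = 0.390, 0.390, 0.224 and 0.390 with an estimated correlation. The shallow library had the lowest share of ribosomal protein counts, 8.17% against 11.3% and 10.9% in the other wild type day 125 libraries and 15.4% to 16.4% at day 25. Without it 53 ribosomal, 43 respiratory chain, 23 mitosis and 17 replication genes fell.

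In the opposite direction, CCNG1, which encodes cyclin G1, rose from 116 ± 17.2 to 326 ± 11 CPM, the DNA repair gene XPC from 72.9 ± 3.84 to 179 ± 8.15, and MDM2, a ubiquitin ligase gene, from 6.08 ± 0.869 to 19.2 ± 4.10. Of the mesenchymal surface markers, 12 of 17 rose and 3 fell (12 and 3 adjusted over the list alone), NT5E (CD73) by 2.17 and ANPEP (CD13) by 3.37 upward, ENG, ALCAM and NES downward. Extracellular matrix genes rose in 20 of 44 members and fell in 5 (20 and 5 adjusted over the list alone), with 3 falling without wild type day 25 replicate 3 or wild type day 125 replicate 1. Fibromodulin, FMOD, rose from 228 ± 6.85 to 1163 ± 95.3 CPM, while the collagen chaperone gene SERPINH1 fell from 290 ± 13.5 to 67.1 ± 4.63. COL1A1 and ACTA2 did not pass the test (0.27 ± 0.14 and 0.20 ± 0.12). By camera, adjusted p was 0.00146 and 0.00279 for these 2 lists, and adjusted p = 0.194 and 0.390 with an estimated correlation. None of the 7 lists called in this comparison stayed called that way. The next 3 lists by camera p were not called (adjusted p = 0.0529, 0.0529 and 0.145), but each was called in some alternatives. The immediate-early and heat shock list was called with no low-count filter, a mean CPM filter, limma-voom, thinning (chosen after seeing the data), and without library knockout replicate 1 or 3 or replicate 2 of either wild-type group (adjusted p over the alternatives 0.0258 to 0.390). The ATF4 list was called with limma-voom, with these groups alone and without library knockout replicate 1 or 2 (0.0145 to 0.584), and the FOXO list after thinning (0.0214 to 0.513). Of 24 immediate-early and heat shock genes 13 rose and 6 fell (13 and 6 adjusted over the list alone; 3 to 5 falling without any 1 library, 3 without wild type day 25 replicate 3), with the chaperone gene HSPH1 at 2.63 ± 0.14 and the stress-response gene IER3 at 1.68 ± 0.12. In the ATF4 amino acid response 5 of 29 genes rose and 14 fell (5 and 14 adjusted over the list alone; 3 rising without wild type day 25 replicate 2 or 3 or wild type day 125 replicate 1), with SHMT2, of mitochondrial serine use, at -1.53 ± 0.12 and the transcription factor gene ATF5 at 1.30 ± 0.13. Of 11 FOXO targets 6 rose and 1 fell (6 and 1 adjusted over the list alone), including PIK3IP1 at 1.89 ± 0.23 and KLF6 at 0.67 ± 0.13.

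**Figure D1:**
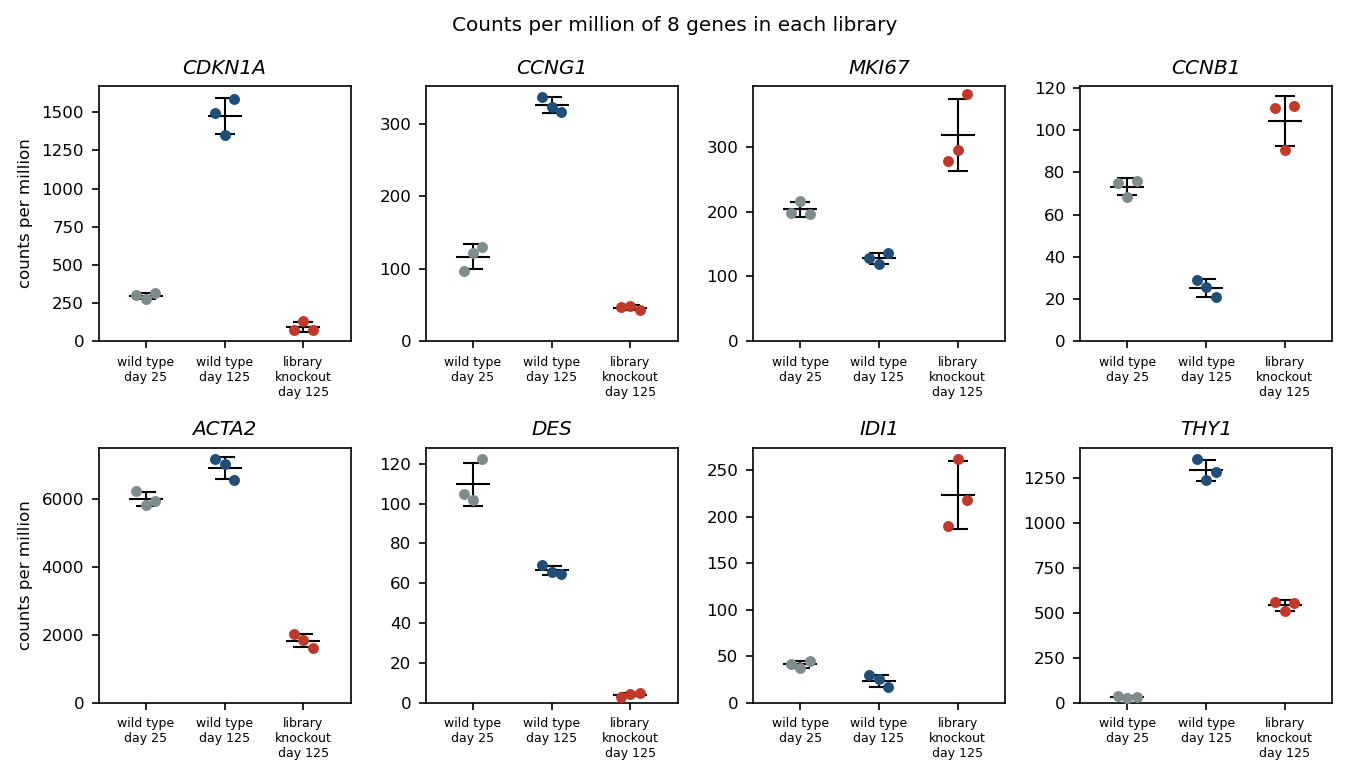
CPM of CDKN1A, CCNG1, MKI67, CCNB1, ACTA2, DES, IDI1 and THY1 (vertical axes, linear) in each of the 9 libraries, by group along the horizontal axis. Points are libraries, and bars are the mean ± SD of 3. CDKN1A averages 1477 in wild type day 125 and 94.2 in library knockout, and CCNG1 averages 326 and 46.5.

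The library knockout population was compared with wild type at the same day to show how the pool differed from unedited cells. Without a transduction control, effects of the vectors or of a library batch cannot be told apart from those of the knockouts. Contractile genes were lower, and cholesterol synthesis genes higher, in the library knockout. Cell-cycle genes were also higher, but their list calls were lost with an estimated correlation (camera adjusted p = 0.0763 and 0.138). DES, the muscle intermediate filament desmin, stood at 4.12 ± 0.974 against 66.5 ± 2.28 CPM (-4.01 ± 0.19, adjusted p = 1.34e-11). ACTA2, smooth muscle actin, stood at 1834 ± 204 against 6925 ± 326 CPM (-1.92 ± 0.12, adjusted p = 6.17e-10). CDKN1A was 94.2 ± 33.8 against 1477 ± 119 CPM (-3.98 ± 0.20, adjusted p = 4.29e-09). MKI67 was 318 ± 55.0 against 128 ± 8.98 CPM and CCNB1 104 ± 11.9 against 25.2 ± 4.07 CPM (adjusted p = 1.11e-07 and 3.84e-09).

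In this comparison 2156 genes were higher and 2121 lower in library knockout, 1880 of them at least 2-fold. Scaling by library totals alone gave 2836 and 1693, or 62.6% higher in place of 50.4%, and moved the median of all genes to 0.19, so directions are relative to TMM scaling. FADS2, the delta-6 fatty acid desaturase, stood at 121 ± 54.6 against 0.966 ± 0.562 CPM (6.93 ± 0.64, adjusted p = 3.85e-05), and EMILIN2, a matrix glycoprotein, at 115 ± 34.6 against 3.24 ± 0.830. RASD2 had 237 counts against 2, a ratio of 71.6 with a 95% counting interval of 19.6 to 595. RPL34 and RPL36AL were also among the 5 largest rises. RPL34 lost its call in limma-voom and when library knockout replicate 1 or 2 or any wild type day 125 library was left out. RAMP3, EDARADD and ALS2CL had 0 counts in the library knockout and 420, 249 and 154 in wild type day 125. Against a floor of 3 counts over the group they were at least 232-fold, 137-fold and 84.9-fold lower. SUSD4 and TCEA3 had 1 count each against 317 and 223, ratios of 524 (93.4 to 20774) and 369 (65.5 to 14633).

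Contractile and myofibroblast genes were lower in 19 of 21 members and higher in 0 (20 and 0 adjusted over the list alone). TPM2, a tropomyosin, stood at 1733 ± 171 against 8968 ± 624 CPM, and TAGLN and CNN1 were at -1.06 and -1.44. Of the pericyte and vascular smooth muscle markers, 5 of 7 were lower and 1 higher (5 and 1 adjusted over the list alone), and MYH11, CNN1 and LMOD1 belong to both lists. YAP/TEAD targets, genes switched on by mechanical tension, were lower in 11 of 16 members and higher in 1 (12 and 1 adjusted over the list alone), including CYR61 (-1.26 ± 0.11) and NT5E (-1.91 ± 0.13). Surface markers of the stem cells were lower in 11 of 17 and higher in 1 (12 and 1 adjusted over the list alone), with integrin beta-1 gene ITGB1 at 488 ± 42.0 against 1962 ± 91.4 CPM. Matrix genes were lower in 24 of 44 and higher in 7 (26 and 7 adjusted over the list alone). Among them THBS1, thrombospondin-1, changed by -3.07 ± 0.14, FN1, fibronectin, by -1.58 ± 0.11 and COL1A1, of type I collagen, by -1.08 ± 0.14. Camera adjusted p was 3.43e-11, 0.0288, 8.14e-05, 0.000736 and 0.000175 for the 5 lists. The contractile (adjusted p = 0.00581 with an estimated correlation), YAP/TEAD and surface marker lists (both 0.0452) kept their call, and the pericyte and matrix lists did not (adjusted p = 0.138 and 0.263 with an estimated correlation). The pericyte call was also lost without library knockout replicate 3 (camera adjusted p = 0.0667).

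Cholesterol synthesis genes were higher in 18 of 22 members and lower in 0 (18 and 1 adjusted over the list alone), with camera adjusted p = 2.47e-07 and adjusted p = 0.0343 with an estimated correlation. IDI1, an isomerase of the mevalonate pathway, stood at 223 ± 36.5 against 23.7 ± 6.42 CPM and DHCR7, which makes cholesterol in the last step, at 218 ± 10.9 against 63.5 ± 1.5. Mitosis genes were higher in 27 of 32 and DNA replication genes in 25 of 33, with 0 lower in either list (27 and 27 higher adjusted over the list alone). MYBL2 was higher by 2.28 ± 0.16, PCNA by 1.57 ± 0.12 and MCM2 by 1.56 ± 0.15. Ribosomal protein genes were higher in 53 of 72 and lower in 0 (56 and 1 adjusted over the list alone), for example RPS25 at 769 ± 14.9 against 260 ± 51.0 CPM. Respiratory chain genes were higher in 30 of 63 and lower in 5 (30 and 5 adjusted over the list alone), with ATP5PO at 0.78 ± 0.13 and COX5A at -0.78 ± 0.13. Among single genes, CCNG1 stood at 46.5 ± 3.50 against 326 ± 11 CPM, XPC at -2.15 ± 0.11 and MDM2 at -2.37 ± 0.29. The camera test gave adjusted p of 3.43e-11, 5.74e-08, 5.18e-09 and 0.0112 for these 4 lists, and adjusted p = 0.0763, 0.138, 0.350 and 0.600 with an estimated correlation. Without the shallow wild type day 125 library, the respiratory chain list was no longer called (camera adjusted p = 0.160), with 27 members higher and 10 lower, and 3 were lower without wild type day 25 replicate 1 or 3.

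Against wild type day 25, the library knockout population showed how the day 125 pool differed from early unedited cells. Contractile genes were again lower and cholesterol synthesis genes higher, while ribosomal protein genes mostly did not pass the test. DES stood at 4.12 ± 0.974 against 110 ± 11 CPM (-4.73 ± 0.18, adjusted p = 1.22e-12), and ACTA2 at 1834 ± 204 against 6019 ± 202 CPM (-1.71 ± 0.12, adjusted p = 5.25e-09). INSIG1, the sterol-sensing regulator of this pathway, stood at 138 ± 25.8 against 19.9 ± 1.77 CPM (2.80 ± 0.16, adjusted p = 3.12e-10). CDKN1A was lower by -1.66 ± 0.19 (adjusted p = 1.45e-05), and MKI67 and CCNB1 were higher by 0.64 ± 0.12 and 0.51 ± 0.12 (adjusted p = 0.000321 and 0.00306).

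Here 1792 genes were higher and 1632 lower in library knockout, 1235 of them at least 2-fold. Scaling by library totals alone gave 2273 and 1259, or 64.4% higher in place of 52.3%, with a median of all genes of 0.14. KCNK12, a potassium channel, stood at 313 ± 34.8 against 7.90 ± 2.91 CPM, FADS2 at 121 ± 54.6 against 1.26 ± 0.773 and MEOX1, a homeobox gene, at 110 ± 43.7 against 2.78 ± 1.75. LHX6 had 256 counts against 3, a ratio of 64.1 (21.7 to 313). ENG was lower at 1.80 ± 0.616 against 109 ± 5.99 CPM and SLC38A5 at 0.731 ± 0.859 against 103 ± 5.33. PARVB and ARHGAP24 had 2 and 3 counts against 515 and 457, ratios of 343 (94.4 to 2836) and 203 (68.9 to 986). VIPR2 (220 counts against 1) was called with all libraries and lost its call when any wild-type library was left out.

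Of 21 contractile genes 18 were lower and 0 higher (18 and 0 adjusted over the list alone), TPM2 at -1.88 ± 0.12. The pericyte markers were lower in 4 of 7 and higher in 1 (4 and 2 adjusted over the list alone), and that list was not called (camera adjusted p = 0.289). Of 22 cholesterol synthesis genes 20 were higher and 0 lower (20 and 0 adjusted over the list alone), IDI1 at 2.43 ± 0.15. Camera adjusted p was 2.32e-12 for contractile and 5.16e-12 for cholesterol genes, and both held (adjusted p = 0.00435 and 0.00786 with an estimated correlation). YAP/TEAD targets were lower in 8 of 16 and higher in 1 (8 and 1 adjusted over the list alone), with CRIM1 at -1.94 ± 0.17 and GADD45B at -1.44 ± 0.17. Mitosis genes were higher in 17 of 32 and replication genes in 15 of 33, with 0 lower in either (18 and 15 higher adjusted over the list alone), including FOXM1 (1.37 ± 0.18), NUSAP1 (0.92 ± 0.14), TYMS (0.68 ± 0.11) and POLA1 (1.01 ± 0.17). Respiratory chain genes were lower in 24 of 63 and higher in 1 (25 and 1 adjusted over the list alone; 3 higher without library knockout replicate 1, 0 without library knockout replicate 2 or wild type day 25 replicate 2 or 3), COX5A at -1.47 ± 0.13 and NDUFS7 at -1.08 ± 0.10. Camera adjusted p was 0.00141, 0.00272, 0.00323 and 0.00101 for these 4 lists, and adjusted p = 0.106, 0.408, 0.408 and 0.528 with an estimated correlation.

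Adipogenesis genes were higher in 10 of 16 and lower in 1 (10 and 1 adjusted over the list alone), with the lipid droplet gene CIDEC at 30.4 ± 10.9 against 3.28 ± 0.152 CPM and the desaturase gene SCD at 95.6 ± 31.6 against 20.4 ± 4.02. FOXO targets were higher in 7 of 11 and lower in 1 (7 and 1 adjusted over the list alone), with the catalase gene CAT at 1.14 ± 0.12 and PIK3IP1, an inhibitor of PI3 kinase, at 1.84 ± 0.22. Interferon response genes were higher in 9 of 23 and lower in 1 (9 and 1 adjusted over the list alone), including IFIT3 (4.34) and ISG15 (1.59). With passage of wild type, 9 interferon genes also rose and 3 fell. In library knockout against wild type day 125, 6 were higher and 4 lower, and the interferon list was not called there (camera adjusted p = 0.528). Genes of the ATF4 amino acid response were lower in 15 of 29 and higher in 4 (16 and 5 adjusted over the list alone; 7 higher without library knockout replicate 1), with DDIT4 at -2.09 ± 0.21 and the stress gene NUPR1 at 2.26 ± 0.16. Glycolysis genes were lower in 10 of 22 and higher in 0 (10 and 0 adjusted over the list alone), with ENO1 at -0.87 ± 0.12 and PGAM1 at -0.87 ± 0.14. By camera, adjusted p was 0.00447, 0.0145, 0.0227, 0.0115 and 0.0145 for these 5 lists, and adjusted p = 0.213, 0.408, 0.213, 0.528 and 0.340 with an estimated correlation. With a filter at a mean of 20 CPM the FOXO and ATF4 lists were no longer called (both 0.0987), and with every library thinned to the smallest total, chosen after seeing the data, the interferon list was not (0.131). Ribosomal protein genes were lower in 6 of 72 and higher in 1 (6 and 1 adjusted over the list alone), and that list was not called (camera adjusted p = 0.289). These counts rest on single libraries: 15 were lower and 4 higher without the shallow wild type day 125 library, 9 and 4 without library knockout replicate 3, 5 and 0 without wild type day 25 replicate 2, and 6 and 0 without replicate 3.

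**Figure D2:**
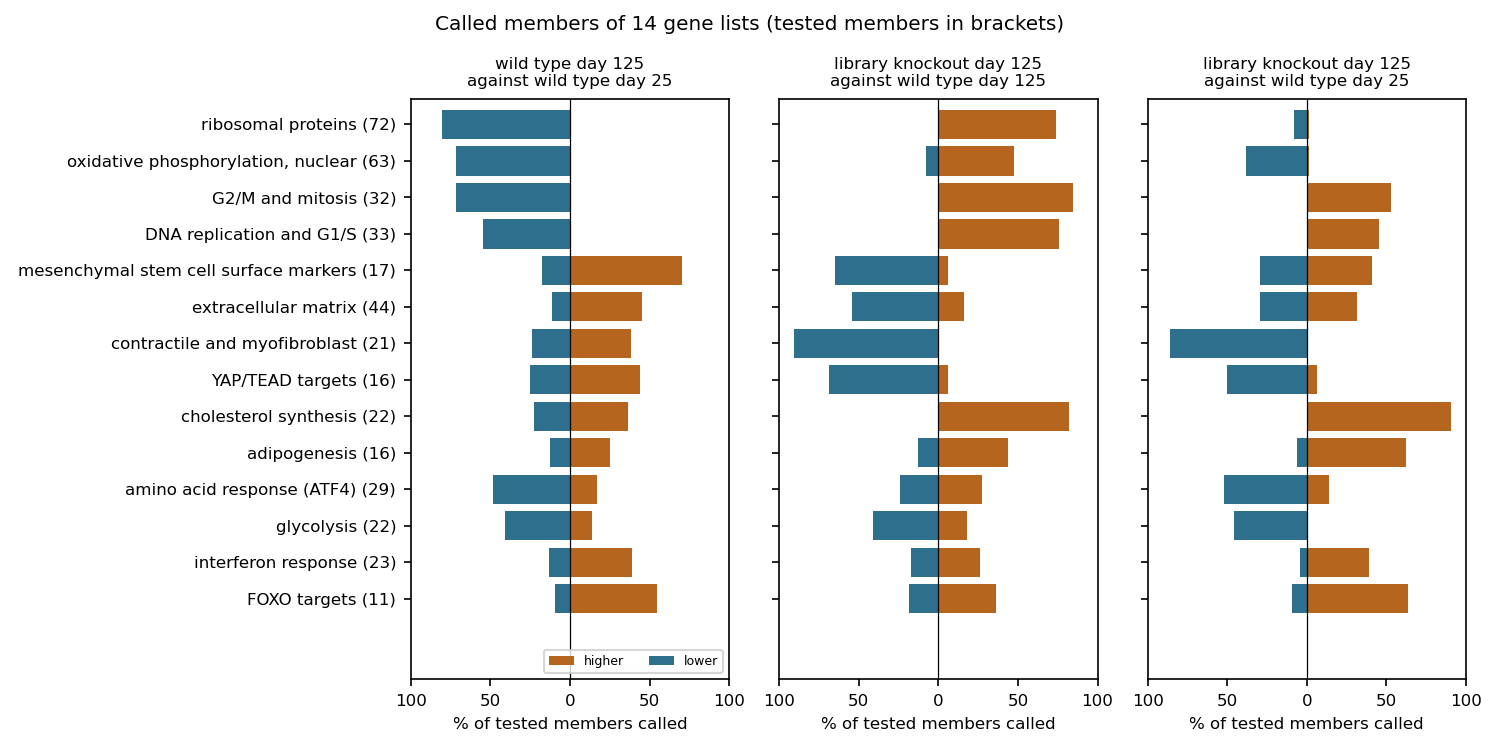
Share of the tested members of 14 gene lists (vertical axis, members in brackets) called higher (brown, to the right) or lower (blue, to the left) in each of the 3 comparisons, in percent on the horizontal axis. Ribosomal protein genes are lower in 58 of 72 members with passage of wild type and higher in 53 in library knockout against wild type day 125, and contractile genes are lower in library knockout in 19 and 18 of 21.

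The passage and library comparisons were set against each other gene by gene. Of 4117 genes that changed with passage in wild type, 2487 (60.4%) changed in the opposite direction between library knockout and wild type day 125, and 219 changed in the same direction. CDKN1A, THY1 and RAMP3 were among those that rose with passage and were lower in library knockout, and MYBL2, CCNB1 and RPL14 among those that fell and were higher. These comparisons share the wild type day 125 libraries. Independent lists of the same sizes would share 994 genes, and in 20 simulations of unchanged groups the mean overlap was 0.2 genes and the highest 1. With no gene changed almost none can be called, so that low overlap was set in advance and does not measure the effect of sharing. The covariance of the fold changes across genes, which are not independent replicates, was -0.825 against -0.0654 simulated, a difference of -0.760. It grows with the size of the fold changes, so unchanged groups had to give a smaller value. The correlation was -0.636 against -0.573, just outside the simulated range (-0.619 to -0.524). In unchanged groups the correlation comes from the shared libraries alone, so it is no baseline for groups that differ in many genes. With 3 libraries per group the shared group could not be split with 2 in each part, so part of the excess overlap may come from the shared controls.

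For library knockout against wild type day 25, which shares the day 25 libraries with the passage comparison, 1592 of the 4117 genes (38.7%) changed in the passage direction and 429 in the other. Independent lists would share 798. FOSB, PAX3 and THY1 were among genes higher in both, and SFRP2, ENG and SLC38A5 among genes lower in both. The covariance, with the same limit, was 0.492 against 0.0533 simulated, a difference of 0.439, and the correlation 0.441 against 0.495. The observed correlation lay below the whole simulated range (0.457 to 0.542). Unchanged groups are no baseline for it here either, so it does not tell whether there was an excess.

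**Figure D3:**
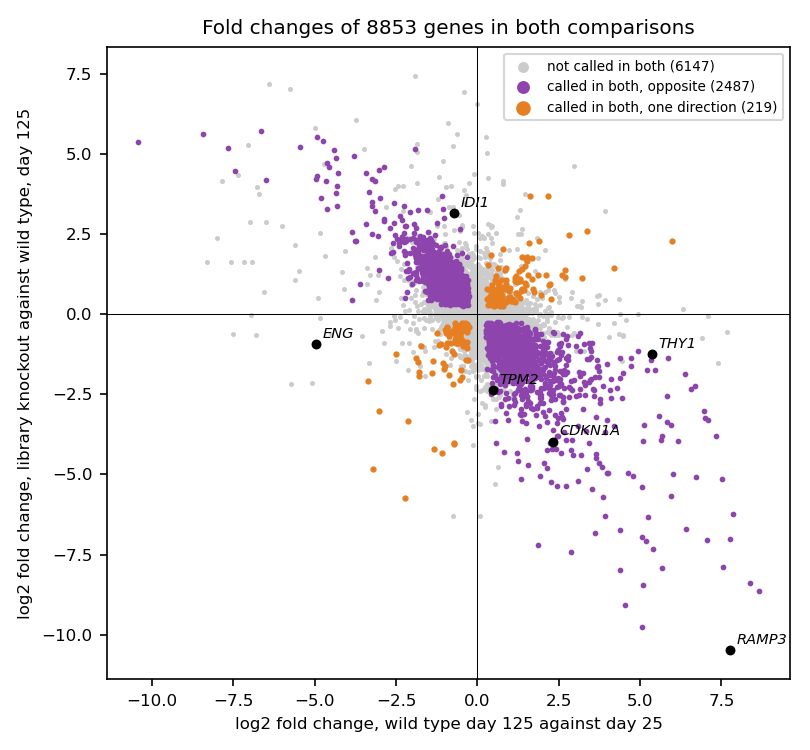
Log2 fold change of 8853 genes in wild type day 125 against day 25 (horizontal axis) and in library knockout against wild type at day 125 (vertical axis). Each point is a gene, and 2487 genes called in both with opposite signs (purple) outnumber 219 called with the same sign (orange); both axes share the wild type day 125 libraries.

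Genes were also grouped by chromosome, since long-cultured cells can gain or lose chromosome parts. Chromosome 21 genes were lower in library knockout than in either wild-type group, with a median of -0.27 over 198 genes against day 125 and -0.28 against day 25 (camera adjusted p = 0.0193 and 0.000296), and neither was called with an estimated correlation (adjusted p = 0.335 and 0.307). Chromosome 8 genes were lower against wild type day 25 (median -0.33 over 246 genes, camera adjusted p = 0.000296), which was also lost that way (adjusted p = 0.795). Against wild type day 125 it was not called, except with a mean CPM filter or without library knockout replicate 1 (camera adjusted p over the alternatives 0.0223 to 0.916). Chromosome 4 genes were higher in wild type day 125 than day 25 (median 0.34 over 245 genes, camera adjusted p = 0.00321) and lower in library knockout than in wild type day 125 (median -0.23, camera adjusted p = 0.0352), with neither called with an estimated correlation (adjusted p = 0.181 and 0.214). The last of these calls was also lost with no low-count filter, after thinning, and without library knockout replicate 1 or 2 or wild type day 125 replicate 1 or 2 (camera adjusted p = 0.0896, 0.0682, 0.0591, 0.0508, 0.0550 and 0.0745). A median as large can go without a call. Chromosome 9 stood at 0.29 over 174 genes in library knockout against wild type day 125 (camera adjusted p = 0.381).

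**Figure D4:**
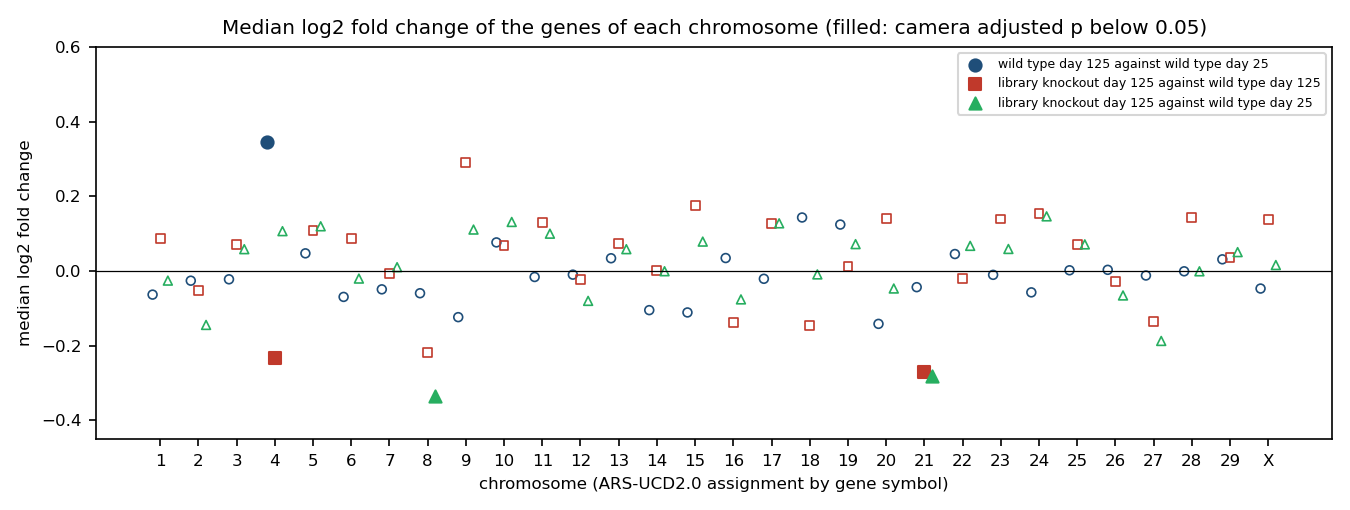
Median log2 fold change of the tested genes of each chromosome (vertical axis) by chromosome (horizontal axis, assigned by symbol in ARS-UCD2.0) in the 3 comparisons, filled where camera with the preset correlation gave an adjusted p under 0.05. Chromosome 21 is at -0.27 and -0.28 in the library knockout comparisons and chromosome 4 at 0.34 in the passage comparison.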

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

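Thinning every library to the smallest total, and list counts and medians without each library, were chosen after seeing the data; the other alternatives were planned. With a correlation between genes estimated from the residuals, 4 gene lists and 0 chromosomes were called for library knockout against wild type day 125, 2 and 0 against wild type day 25, and 0 and 0 for passage of wild type. The cause was not tested. For library knockout against wild type day 125, 1 chromosome was called with no low-count filter and 1 after thinning, and the cause was not tested. After thinning, 1164 genes were higher against wild type day 25, with 7115 genes tested in place of 8853. Leaving out 1 library at a time gave, for library knockout against wild type day 125, 1829 to 2138 genes higher, 1812 to 2103 lower, 10 to 12 lists and 1 to 2 chromosomes. Against wild type day 25 it gave 1387 to 1889 higher, 1326 to 1726 lower, 11 to 12 lists and 2 chromosomes, and for passage 1786 to 2316, 1633 to 2114, 7 to 9 lists and 1 chromosome. Genes opposite to passage ran from 2028 to 2526. DESeq2 called 1785 higher and 1900 lower, 1427 and 1443, and 1855 and 1714 in the 3 comparisons. With a filter at an arithmetic mean of 20 CPM before TMM scaling, 5175 genes were tested and 916, 560 and 866 changed at least 2-fold. Libraries with equal replicate numbers had correlations of deviations from -0.043 to 0.168 (median 0.042). These lay inside the range for unequal numbers (-0.235 to 0.178, median -0.017), so no clear pairing was seen and a weak one is not excluded. A replicate block gave 2148 and 2096, 1783 and 1629, and 2097 and 1990 genes. Across these settings 2069 values of named genes kept direction and side of the threshold, 24 fell short of it and 5 newly passed it. For gene lists the counts were 1451, 28 and 24. Of the chromosomes only 21, 8 and 4 were followed, with counts of 176, 11 and 2. None of these named genes, lists or chromosomes past the threshold in either setting turned direction. Counts of 0 or 1 list members also moved by 1 without some library. Medians of lists that were not called crossed 0 when 1 library was left out, for library knockout against wild type day 125 in Wnt (-0.41 to 0.04), glycolysis (-0.31 to 0.03), FOXO (-0.02 to 0.27) and ATF4 genes (-0.03 to 0.28), against wild type day 25 in Wnt genes (-0.23 to 0.36) and secreted factors of senescence (-0.13 to 0.05), and for passage in HOX (-0.09 to 0.08), pericyte (-0.02 to 0.29) and antigen presentation genes (-0.0062 to 0.06). Which direction held more genes also turned. For passage, more genes fell than rose with upper-quartile factors (1976 rose and 2173 fell), library totals (2003 and 2121) and no filter (2097 and 2179). For library knockout against wild type day 125, more were lower with RLE factors (2107 higher and 2148 lower), DESeq2, limma-voom (2063 and 2190), these groups alone (1868 and 1968) and some libraries left out. Against wild type day 25, more were lower with upper-quartile factors (1671 and 1779), DESeq2 and without wild type day 25 replicate 2 (1387 and 1413).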

Other observations

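The lists that were not called as a whole in the report held genes with large changes, and the members named here were chosen after their values were seen. Of 9 Wnt pathway genes, 5 rose and 1 fell with passage, and 2 were higher and 5 lower in library knockout than in wild type day 125. Without the shallow library or any 1 wild type day 25 library, 12 genes were tested and 4 were higher. SFRP2, a secreted Wnt antagonist, stood at 5566 ± 300.1 CPM in wild type day 25, 453 ± 29.5 in wild type day 125 and 858 ± 155 in library knockout, while DKK2, another antagonist, stood at 41.7 ± 9.50, 228 ± 9.43 and 16.1 ± 7.38. The chaperone gene HSPH1 stood at 28.7 ± 2.33, 177 ± 9.76 and 18.4 ± 3.32 CPM, and the transcription factor gene FOSB at 5.80 ± 1.45, 111 ± 44.8 and 87.0 ± 7.12. Of 19 secreted factors of senescence, 5 were higher and 10 lower in library knockout than in wild type day 125, and the list was called there after thinning (camera adjusted p over the alternatives 0.0408 to 0.346). IGFBP7, which binds insulin-like growth factors, stood at 388 ± 16.9, 572 ± 96.8 and 35.1 ± 11.1 CPM. CXCL5, a neutrophil chemokine, ran the other way, at 79.5 ± 2.67, 3.49 ± 0.819 and 80.8 ± 45.3.

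Of 33 HOX and positional genes, 8 were higher and 12 lower in library knockout than in wild type day 125, and 10 rose and 11 fell with passage. Without wild type day 125 replicate 2, 5 were higher in library knockout and 7 fell with passage. EN1, a homeobox gene of dorsoventral patterning, stood at 40.1 ± 1.87 CPM in wild type day 25, 38.8 ± 5.08 in wild type day 125 and 12.2 ± 1.26 in library knockout. Of 15 antigen presentation genes, 6 were higher and 2 lower in library knockout than in wild type day 125, with B2M, the light chain of class I molecules, at 282 ± 20.6, 166 ± 24.1 and 470.3 ± 31.0. Against wild type day 25 that list was called with limma-voom and without library knockout replicate 2 (camera adjusted p over the alternatives 0.0386 to 0.272). Of 20 NRF2 targets, 7 were higher and 3 lower in library knockout than in wild type day 125. In that comparison 1 of 8 bone and cartilage genes was higher and 5 lower, including the homeobox gene MSX1 at 50.1 ± 2.64, 103 ± 9.31 and 26.3 ± 5.91. The bone and cartilage list had camera adjusted p = 0.0640 against wild type day 125. There it was called with library totals, limma-voom, these groups alone and thinning. It was also called without library knockout replicate 1 or 2 or wild type day 125 replicate 2 (camera adjusted p over the alternatives 0.00215 to 0.182). For passage it was called after thinning (0.0162 to 0.390). Of 18 growth-restraining genes, 3 were higher and 6 lower in library knockout than in wild type day 125. These counts were 1 and 4 without wild type day 125 replicate 2, and 4 were lower without library knockout replicate 2 or the shallow library.

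The tests of depth without the shallow library, of a few strongly changed genes, of loss of a whole chromosome, of the shallow library and of composition scaling were chosen after the result was seen. The 6 libraries of a comparison make 10 splits, too few for a share under 0.05. The real split gave 4277, 3424 and 4117 changed genes for library knockout against day 125, against day 25 and for passage, and the highest other split gave 0, so 1 split in each gave as many. For gene lists, 3, 1 and 3 splits gave as many as the real 11, 11 and 7, with 11, 10 and 8 the highest other. For chromosomes, 7, 6 and 2 splits gave as many as the real 2, 2 and 1, with 3, 5 and 1 the highest other. Of 100 drawn splits of the 9 libraries, 1, the real one, gave as many as 2487 genes opposite to passage. The highest other gave 1555 and also kept the 3 wild type day 125 libraries together as the shared group. Splits that mix the groups widen the spread within groups, so the real split was likely to rank first. The ranking therefore cannot exclude chance for the size of the overlap. Much of the overlap can come from wild type day 125 differing from both other groups, a difference that the split with 1555 genes also keeps.

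Library knockout libraries differed from one another by 6.62 to 10.3 chi-square per degree of freedom, wild-type replicates by 1.75 to 5.50, and 62 of 5494 genes lay over 4-fold apart in the library knockout against 8 of 5283 and 6 of 5426 in wild type day 25 and 125. Thinned to 977453 counts, library knockout pairs ran from 3.12 to 4.24, and all wild-type pairs without the shallow library lay lower (1.31 to 1.83 at day 25, 1.60 at day 125). The gap of 1.29 that stayed argues against depth as the cause there. Pairs with the shallow library ran from 3.95 to 4.57 after thinning. Library knockout pairs thus did not differ more than these at equal totals, and depth stays open for the gap to them before thinning. Wild-type cells as most of replicate 1 are argued against by its median position of 0.901 (quartiles 0.713 to 1.09) between wild type (0) and the other library knockout libraries (1), against 0.974 and 0.850 for replicates 2 and 3, and a smaller share of them stays open. For the gap to pairs without the shallow library, different sets of knockout clones in each library stay open as a hypothesis, since guide counts were not analysed here.

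Genes of chromosome 21 were lower in all 3 library knockout libraries (medians -0.39, -0.31 and -0.30 against the wild type day 25 mean). A few strongly changed genes as the whole cause are argued against by the 69.2% of genes below 0, where random sets gave 40.9% to 54.5%. Expression level alone is argued against by 0% of 10000 matched sets being as low (lowest median -0.13). Random sets carry no correlation between genes of 1 chromosome, and chromosome 21 was picked for its low values in these data. Neither comparison therefore tests whether the shift is chance. Loss of the whole chromosome in part of the cells stays open: medians of its 4 equal parts ran from -0.66 to -0.018 over the library knockout libraries, unevenly, and the highest lies inside the wild-type spread, where the last part was also lower at day 125 (-0.16, -0.11 and -0.12). Transcript counts do not measure copy number, and with an estimated correlation the chromosome was not called (adjusted p = 0.307). The shift was not particular to chromosome 21: chromosome 8 was also lower in all 3 library knockout libraries (medians -0.22, -0.35 and -0.48).

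Ribosomal protein genes were lower in wild type day 125 than day 25, with a median of -0.74. The shallow library as the whole cause is argued against by a median of -0.62 without it (camera adjusted p = 6.12e-12), and composition scaling by medians from -0.74 to -0.79 over 4 other scalings. High expression is argued against by 0% of 10000 matched lists being as low (lowest median -0.31). The lists were matched in broad bins of expression, so an effect limited to the very highest expressed genes stays open. With an estimated correlation of 0.51 between these genes the list was not called (adjusted p = 0.390), and a library batch that coincides with the wild type day 125 group cannot be told apart from passage. Slower growth of late unedited cells, with lower mitosis genes and higher CDKN1A beside it, may contribute but was not measured.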
